A study of Homo sapiens with 18 samples.

How the data were processed

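RNA was sequenced from 3 lines of THP-1, an established human monocytic leukaemia cell line that phorbol 12-myristate 13-acetate (PMA) turns into macrophage-like cells. Per the labels, the lines carried an empty vector (EV), Siglec-5 (S5) or Siglec-14 (S14). Siglec-5 and Siglec-14 are sialic acid-binding receptors of myeloid cells with nearly identical outer domains; Siglec-5 carries an inhibitory tail and Siglec-14 pairs with the activating adaptor DAP12, which TYROBP encodes. Per the labels' protocols, cells received 100 nM PMA for 24 h and then either mock medium or 50% medium conditioned by SW620, an established colorectal cancer line, for 48 h. Total RNA was isolated with NucleoZol and libraries were made with a TruSeq Stranded mRNA kit, per the labels' protocols. The 6 groups (3 lines, each in mock or conditioned medium) held 3 libraries each, 18 in all, and each library was placed in its group by its title.

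The deposited table gave raw read counts per gene for each library, made by the authors with HISAT2 on genome build GRCh38, per the submitters' processing notes. The same table held TPM values as deposited by the authors, which entered no result given here. The HISAT2 version, the counting program, the annotation release, the strand setting of the counting and any filter are not given in the sources used here. Reads of antisense neighbours and of overlapping or near-identical genes therefore cannot be assigned with certainty. The table listed 60623 genes, of which 16083 had no symbol, and 58516 identifiers (96.5%) were found in GENCODE release 29, from which gene positions on GRCh38 were taken.

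Each library's counts were scaled with TMM factors, and expression is given as CPM, counts scaled to a total of 1 M after that step, as mean ± SD over 3 libraries unless stated. Intervals and floors (3 counts in a library, for a gene without counts) cover counting error only, since reads without molecular identifiers are not independent molecules.

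Genes were kept by the default expression filter of edgeR applied by group, which left 17851. A quasi-likelihood model with robust dispersion estimates was fitted to all 18 libraries with 1 mean per group (edgeR 4.0.16, limma 3.58.1, R 4.3.3). From it, 12 comparisons were tested: conditioned against mock medium in each line, each pair of lines within each medium, and the 3 differences between lines in their response to conditioned medium. P-values were adjusted by Benjamini and Hochberg's method within each comparison, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with their standard errors.

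The design, the alternatives and 30 gene lists were fixed before the data were examined. The lists were the Siglec family, ITAM and ITIM signalling, sialic acid metabolism, inflammatory cytokines and chemokines, NF-kB target regulators, interferon-stimulated genes, alternative activation and tumour-associated macrophage markers, macrophage identity and scavenging, immune checkpoint and T cell regulatory ligands, MHC class II, MHC class I, matrix remodelling, hypoxia response, glycolysis, oxidative phosphorylation, cholesterol biosynthesis, LXR targets and lipid storage, the integrated stress response with amino acid supply, ER chaperones, NRF2 targets, metallothioneins, cell cycle and DNA replication, p53 targets, immediate early genes, ribosomal proteins, colorectal epithelial markers, immature myeloid markers, lymphocyte markers, mitochondrially encoded genes and replication-dependent histones. Each list with at least 5 tested members was compared with the other genes by limma's camera with a preset inter-gene correlation of 0.01 on log2 CPM (prior count 2), and adjusted over the lists of a comparison. Members called are counted over all genes tested and "adjusted over the list alone". Camera was repeated with an estimated correlation, and limma's fry tested whether a list moved on balance in 1 direction.

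Named genes followed a fixed rule. For each conditioned medium comparison it took up to 8 called genes with the largest rises and 8 with the largest falls, and for each pair of lines or each difference in response 5 and 5. These genes had a mean of at least 10 CPM in the highest group and, outside the differences in response, no overlap between the libraries of both groups. Clone names, LOC, LINC, MIR, SNOR and antisense genes, pseudogenes, readthroughs, Y-linked genes and XIST were passed over, and SIGLEC5 and SIGLEC14 were given in any case. For each list it took up to 4 members with the smallest p in the comparison described and at least 1 CPM in the higher group. For lists described across the lines these were taken from the EV comparison. Uncalled members were named where a list had no called member. Exceptions are marked as chosen after their values were seen, and some genes the rule took are not reported here.

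The titles number the replicates 1 to 3 in every group. Deviations from the group means of log2 CPM correlated at 0.155 to 0.794 between same-numbered libraries of different groups (45 pairs), and at 0.144 to 0.51 between libraries numbered 1 and 2, and 13 of 18 libraries had a best partner of their own number. The pairing was therefore taken from the titles, and the check does not show it for replicates 1 and 2. A model with replicate numbers as a block was set down with the design. Libraries of replicate 3 deviated together (correlations of 0.384 to 0.794 over 15 pairs). Values from replicates 1 and 2 alone were therefore added after seeing the data, as were a replicate block within each line and the block with an estimated correlation. The other alternatives were relative log expression and upper-quartile scaling, no expression filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, and the omission of each library in turn.

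The procedure was tested on simulated counts with 200 changed genes for conditioned against mock medium in the EV line (17457 genes). It recovered 56% of 2-fold and 87% of 4-fold changes, with 5 false calls among 148. Replicate 3 was then given a shift, the same in every group, that need not match the data (17229 genes). The spread between libraries was also set well below the data's. The next recoveries thus cannot be compared with those above or taken as the power here. Recovery was 61% and 93% without the block (0 false calls among 154) and 100% of both with it (13 among 213). In simulated lists camera called the 1 raised list (adjusted p = 7.48e-10) and 0 of 29 others. They were random genes simulated independently, no check on lists whose members move together. No list was added to those fixed at the start.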

Results

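Gene expression was measured by RNA-seq in PMA-treated THP-1 lines carrying an empty vector (EV), Siglec-5 (S5) or Siglec-14 (S14), kept in mock medium or in medium conditioned by SW620 colorectal cancer cells (conditioned medium, CM in names of libraries). Each of the 6 groups held 3 libraries. Mean totals were 21.9 ± 3.24 M counts in EV mock, 21.9 ± 0.666 in S5 mock, 21.8 ± 0.787 in S14 mock, 21.7 ± 2.95 in EV conditioned medium, 20.3 ± 3.98 in S5 conditioned medium and 21.1 ± 5.64 in S14 conditioned medium (SD, n = 3 each). Single libraries ranged from 15.0 M (S14 conditioned medium, replicate 1) to 26.05 M (S14 conditioned medium, replicate 3). The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

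Across the 18 libraries, the S14 line stood apart from EV and S5 on the first principal component (43.3% of the variance). Replicate 3 stood apart from replicates 1 and 2 on the second (23.6%), in every group. Within groups, replicates 1 and 2 differed by a chi-square of 3.58 to 20.4 per degree of freedom (6 pairs), and replicate 3 differed from them by 50.9 to 166 (12 pairs), so no pair lay within sampling noise. Mitochondrially encoded mRNAs made up 4.26 ± 0.237% of counts in replicate 3 (n = 6) and 2.77 ± 0.674% in replicates 1 and 2 (n = 12). They were 1.59%, 1.49% and 4.52% in the S14 mock libraries. Replicate 3 was also deeper (24.3 ± 1.45 against 20.02 ± 2.28 M counts). Values from replicates 1 and 2 alone, a choice made after seeing the data, and from a fit with the replicate number as a block are therefore given beside results they change.

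**Figure D1:**
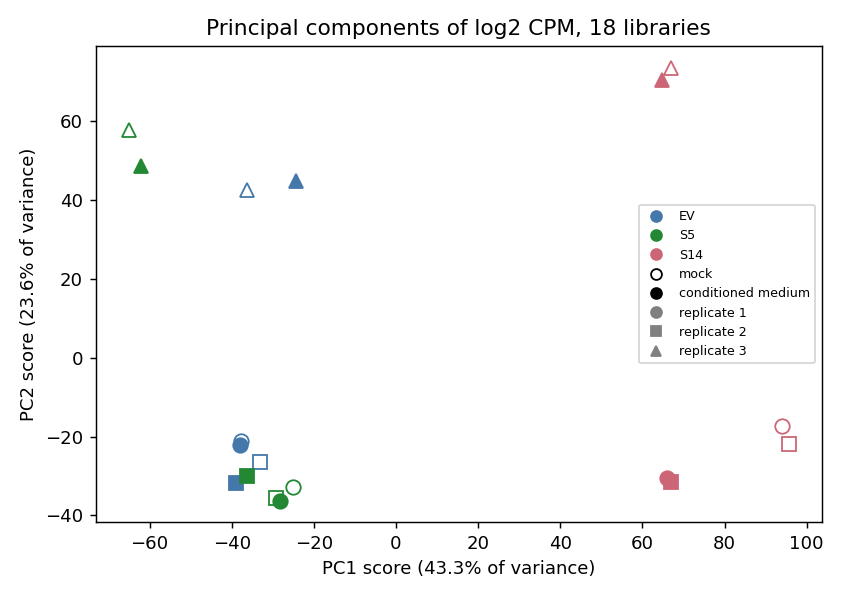
Principal components of log2 CPM over 18 libraries, with PC1 (43.3% of the variance) on the x axis and PC2 (23.6%) on the y axis, coloured by line and marked by medium, with each point's replicate number.

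To determine whether the lines expressed the receptors they are named for, counts of SIGLEC14 and SIGLEC5 were examined in every library. SIGLEC14 (ENSG00000254415, chromosome 19, 51642553 to 51646801, minus strand, GRCh38) was far higher in the S14 line than elsewhere. It reached 779 ± 198 CPM in S14 mock cells, 38.6 ± 7.76 in S5 and 17.7 ± 4.13 in EV (SD, n = 3), and 663 ± 143, 36.4 ± 6.42 and 20.02 ± 3.42 in conditioned medium. S14 exceeded EV 43.9-fold in mock and 33.1-fold in conditioned medium (edgeR, log2 fold change 5.46 ± 0.29, adjusted p = 9.23e-08, and 5.05 ± 0.29, adjusted p = 1.53e-07). S5 cells also held 2.18 times the EV level in mock and 1.82 times in conditioned medium, with no overlap between the 6 S5 libraries (29.5 to 44.1 CPM) and the 6 EV libraries (13.0 to 22.7). By edgeR this S5 difference was not significant (1.12 ± 0.25, adjusted p = 0.969 in mock, 0.86 ± 0.25, adjusted p = 1 in conditioned medium). With the replicate block it was called in mock (adjusted p = 0.0246) and not in conditioned medium (adjusted p = 0.112). The exact two-sided permutation p was 0.1 for each of these 4 comparisons of a line with EV, the smallest possible here.

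SIGLEC5 (ENSG00000105501, chromosome 19, 51611927 to 51645545, minus strand), which encodes the inhibitory receptor, was counted at only 0.614 ± 0.228 CPM in S5 mock cells and 0.902 ± 0.248 in EV mock cells (exact two-sided permutation p = 0.2). In conditioned medium it was 0.748 CPM in S5 and 0.522 in EV cells, with no overlap of CPM between libraries (exact two-sided permutation p = 0.1). The raw counts did overlap, at 14 to 17 per library in S5 and 8 to 16 in EV conditioned medium. Per library the mock counts were 10 to 20 counts in S5 mock, 14 to 24 in EV mock and 0 to 11 in S14 mock. A second gene model of the same name (ENSG00000268500, 51612091 to 51646889) held 4 to 6 counts in S5 mock and 3 to 6 in S5 conditioned medium, 2 to 8 in S14 mock, and 0 in every EV and S14 conditioned medium library. In GENCODE 29, 100% of the 1554 windows of 100 bases in the SIGLEC5 coding sequence overlapped another gene model, and 34.9% occurred unchanged in SIGLEC14. How the counting treated shared reads is not given in the sources used here, so SIGLEC5 levels, and SIGLEC14 levels in S5 cells, are uncertain.

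**Figure D2:**
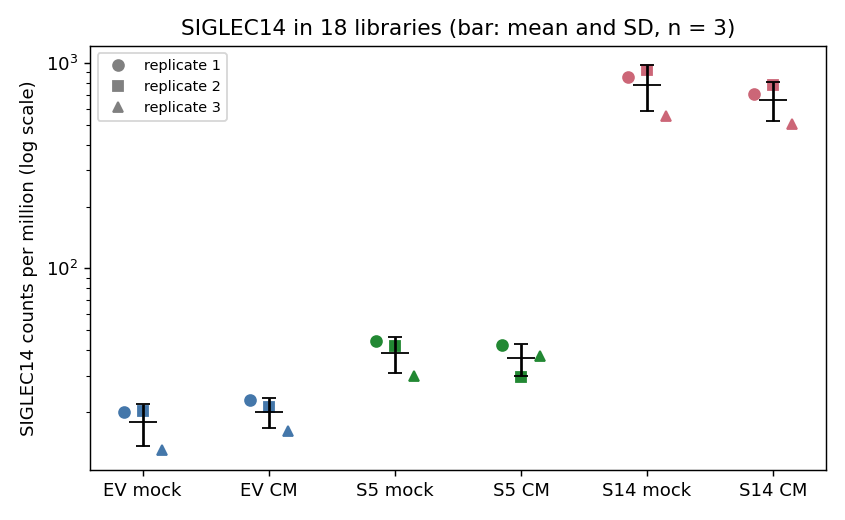
SIGLEC14 expression in CPM (log axis) for each library by line and medium, with group mean and SD. S14 libraries lie between 503 and 926 CPM.

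To ask how Siglec-14 cells differed from empty-vector cells before any exposure to tumour medium, S14 and EV mock groups were compared. F13A1, the factor XIII A subunit of monocytes and macrophages (chr6, 6144085 to 6321013), stood at 0.148 CPM against 27.7 ± 7.80 (log2 fold change -7.48 ± 0.58, adjusted p = 1.31e-06). MPEG1, which encodes the pore-forming perforin-2 (chr11, 59208510 to 59212951), fell to 1.62 CPM from 62.6 ± 17.9 (-5.26 ± 0.46, adjusted p = 3.74e-06). The complement gene C1QA (chr1, 22636506 to 22639608; -5.09 ± 0.42), the chemokine receptor CCR2 (chr3, 46353734 to 46360928; -4.95 ± 0.73) and GPR34 (chrX, 41688973 to 41697277; -5.16 ± 0.55) were also lower. The largest gains were in IGFN1 (chr1, 201190825 to 201228952; 95.6 ± 35.5 against 0.289 ± 0.0912 CPM, 8.34 ± 0.59, adjusted p = 7.19e-07), INHBA, the activin A subunit (chr7, 41667168 to 41705834; 6.95 ± 0.87), TRIM54 (chr2, 27282392 to 27307439; 6.87 ± 0.97) and SDS, serine dehydratase (chr12, 113392445 to 113426301; 6.85 ± 0.72). ATP1B4 (chrX, 120362085 to 120383249) held 15.1 ± 14.0 CPM and no count in any EV mock library, at least 115-fold higher against a floor of 3 counts per library.

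By edgeR, 3575 of 17851 genes differed between S14 and EV mock cells, 1976 higher and 1599 lower, and 1127 and 995 of these by at least 2-fold. The count was 6672 (3346 higher, 3326 lower) with the replicate block and 9921 in replicates 1 and 2 alone. It was 2264 without EV mock replicate 1, 2315 without S14 mock replicate 1 and 2318 without S14 mock replicate 2. With upper-quartile scaling, which moved the median of all genes from -0.02 to -0.12, 44.3% of called genes were higher, against 55.3%.

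Interferon-stimulated genes were higher in S14 mock cells as a group (median log2 fold change 0.82 over 43 members, camera adjusted p = 2.49e-10). This was the only list in the comparison called with an estimated correlation (adjusted p = 0.048, 0.122 with the block), and not in replicates 1 and 2. Of its members 22 rose and 0 fell, or 27 and 0 adjusted over the list alone. Among them were OAS2, which makes the activator of RNase L (1.73 ± 0.18), and the translation inhibitors IFIT1 (2.38 ± 0.32), IFIT2 (1.91) and IFIT3 (2.21 ± 0.25, 21.1 against 4.56 CPM). Inflammatory cytokines and chemokines were also higher (median 1.76, adjusted p = 0.000115, and 0.359 with an estimated correlation). Of 23 members 9 rose (11 adjusted over the list alone). CSF1, the macrophage growth factor, reached 547 ± 103 CPM against 6.32 ± 4.01 (6.43 ± 0.63, adjusted p = 8.7e-06), LIF rose by 5.54 ± 0.95 and CCL5 by 1.15 ± 0.23. NF-kB regulators followed (median 0.89, adjusted p = 0.000122, and adjusted p = 0.284 with an estimated correlation), with 12 higher and 2 lower (13 and 2 adjusted over the list alone), including NFKB2 (1.61 ± 0.24), BCL2A1 (2.64 ± 0.41) and CD40 (1.04 ± 0.21).

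Immediate early genes had 12 members higher and 2 lower of 26, or 16 and 2 adjusted over the list alone (median 1.07, adjusted p = 6.61e-05, and adjusted p = 0.284 with an estimated correlation). They included EGR1 (2.26 ± 0.40), JUNB (1.52 ± 0.19) and DUSP5 (3.17 ± 0.38) among the rises and ETV5 (-0.999 ± 0.151) among the falls. Matrix remodelling genes had 11 of 36 higher and 2 lower, or 16 and 3 adjusted over the list alone (median 1.15, adjusted p = 0.00016, and adjusted p = 0.284 with an estimated correlation). The metalloproteinase MMP19 stood at 420 against 31.8 CPM (3.72 ± 0.36). Glycolysis genes rose in 11 of 20 cases, 13 adjusted over the list alone (median 0.75, adjusted p = 6.37e-05, and adjusted p = 0.184 with an estimated correlation), among them the glucose transporter SLC2A1 (468 against 153 CPM, 1.61 ± 0.29). Hypoxia response genes rose in 11 of 23 cases, 12 adjusted over the list alone (median 1.05, adjusted p = 6.3e-06, and adjusted p = 0.359 with an estimated correlation), such as CA12 (5.18 ± 0.74). NRF2 targets had 9 of 19 higher and 1 lower, 12 and 2 adjusted over the list alone (median 0.92, adjusted p = 0.000315, and adjusted p = 0.284 with an estimated correlation), with SQSTM1 at 827 against 246 CPM (1.75 ± 0.24).

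Immature myeloid markers were lower in S14 mock cells (median -1.64, adjusted p = 9.25e-05, and 0.359 with an estimated correlation). Of 14 members 0 rose and 6 fell, or 10 adjusted over the list alone, including the transcription factor MYB (4.81 against 76.3 CPM, -3.99 ± 0.66) and the granule ribonuclease RNASE3 (-2.05 ± 0.34). All 11 MHC class II genes had lower estimates (median -0.90, adjusted p = 0.00152, and adjusted p = 0.147 with an estimated correlation). Of these 4 fell, or 6 adjusted over the list alone and 9 with the replicate block. HLA-DRB1 stood at 43.7 against 80.6 CPM (-0.88 ± 0.19, adjusted p = 0.004, and 0.059 in a fit of these groups alone). Cell cycle genes had lower estimates in 39 of 40 cases (median -1.14, adjusted p = 2.06e-05, and adjusted p = 0.504 with an estimated correlation). None of them fell by the gene test, adjusted over all genes or over the list alone, against 37 with the replicate block. Their median was -2.77, -2.93 and -0.35 in replicates 1, 2 and 3, alongside the mitochondrial shares given above for these libraries. The 1 called member was CCND1, cyclin D1, which was higher (341 against 70.8 CPM, 2.27 ± 0.35).

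Alternative activation markers were lower on balance (median -0.83, adjusted p = 0.0356, and adjusted p = 0.359 with an estimated correlation), with 6 higher and 9 lower, or 6 and 11 adjusted over the list alone. FOLR2, a folate receptor of resident macrophages, fell by 4.20 ± 0.34 on the log2 scale. LYVE1 held 2.04 ± 0.377 CPM in EV and no count in S14, at least 13.7-fold lower against a floor of 3 counts per library. IL1RN, the interleukin-1 receptor antagonist, went the other way (2887 ± 213 against 92.0 ± 6.13 CPM, 4.97 ± 0.33). The list's call was lost with the block (adjusted p = 0.0532), without S14 mock replicate 3 (0.0649), in replicates 1 and 2 (0.197), in a fit of these groups alone (0.0547) and with upper-quartile scaling (0.0747). MHC class I genes were higher (median 0.32, adjusted p = 0.0183, and adjusted p = 0.388 with an estimated correlation), 4 rising and 1 falling with either adjustment, HLA-F by 1.39 ± 0.23 and TAPBPL by -0.70 ± 0.16, and the call was lost without S14 mock replicate 3 (0.107). Ribosomal protein genes were lower (median -0.23, adjusted p = 0.0213, and adjusted p = 0.616 with an estimated correlation), 1 being called over all genes and 0 adjusted over the list alone. That call was lost without EV mock replicate 3 (0.364) or S14 mock replicate 1 (0.177) or 2 (0.108).

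The other lists were not called in S14 against EV mock cells. Their adjusted p and counts higher and lower were 0.0547 with 6 and 0 for the integrated stress response, 0.066 with 4 and 0 for ER chaperones, and 0.071 with 3 and 8 for ITAM and ITIM signalling. LXR targets gave 0.114 with 6 and 1, checkpoint ligands 0.22 with 6 and 4, the Siglec family 0.22 with 1 and 3, p53 targets 0.355 with 5 and 2, and sialic acid metabolism 0.507 with 3 and 3. Lymphocyte markers, oxidative phosphorylation, cholesterol biosynthesis, metallothioneins, mitochondrially encoded genes and histones gave 0.066 to 0.363. Macrophage identity genes had 2 higher and 10 lower (adjusted p = 0.066), with a median of 0.17, a mean of -0.69 and a test pointing down.

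To ask whether the lines also differed in tumour-conditioned medium, S14 and EV cells in that medium were compared. F13A1 (-8.05 ± 0.63), MPEG1 (-4.59 ± 0.45) and C1QA (-3.42 ± 0.39) were again lower in S14, as were C1QC (chr1, 22643630 to 22648110; -3.24 ± 0.38) and LRRC4 (chr7, 128027071 to 128032107; -3.19 ± 0.42). IGFN1 (155 ± 20.2 against 0.443 CPM, 8.40 ± 0.58), FA2H, a fatty acid hydroxylase (chr16, 74712955 to 74774831; 7.49 ± 1.09), and CCR7, the lymph node homing receptor (chr17, 40553769 to 40565472; 12.7 against 0.124 CPM, 6.66 ± 0.69), were higher. HES2 (chr1, 6412418 to 6424670) held 17.0 ± 1.97 CPM in S14 and no count in EV, at least 127-fold higher against the same floor. ATP1B4 held 15.9 ± 10.7 CPM against 1 count in all EV libraries together, a ratio of 1077 (exact Poisson 95% interval 193 to 42553).

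By edgeR, 1990 genes differed between S14 and EV cells in conditioned medium, 1329 higher and 661 lower, and 910 and 359 by at least 2-fold. With the replicate block 4207 were called, 54.8% of them higher against 66.8% without it, and in replicates 1 and 2 alone 7825, 47.6% of them higher. Without EV CM replicate 1 or 2 the count was 1164 and 1173. Interferon-stimulated genes were again higher (median 0.87, adjusted p = 1.26e-14, and 0.0125 with an estimated correlation, a call lost in replicates 1 and 2). Of these 22 rose, or 28 adjusted over the list alone, such as OAS2 (1.67 ± 0.18) and LY6E (127 against 28.2 CPM, 2.17 ± 0.29). All 29 genes of the integrated stress response and amino acid supply had higher estimates (median 1.51, adjusted p = 7.86e-11, and adjusted p = 0.294 with an estimated correlation). Of these 14 rose, or 24 adjusted over the list alone, among them the stress transcription factor DDIT3 (122 against 26.6 CPM, 2.19 ± 0.27), the tryptophanyl-tRNA synthetase WARS1 (560 against 126 CPM, 2.16 ± 0.29) and CEBPB (2.11 ± 0.31). The median of this list was 1.79, 1.47 and 0.25 in replicates 1, 2 and 3.

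Further lists were called in S14 against EV cells in conditioned medium with the preset correlation and lost with an estimated one (adjusted p = 0.294 to 0.667 with an estimated correlation). Higher lists were immediate early genes (adjusted p = 1.33e-05, 10 rising and 1 falling, 14 and 2 adjusted over the list alone), hypoxia response (2.41e-05, 5 rising, 11 over the list alone), matrix remodelling (8.77e-05, 10 rising, 15 and 1 over the list alone) and inflammatory cytokines (0.000109, 6 rising, 7 over the list alone). CSF1 reached 691 against 7.39 CPM (6.54 ± 0.64), MMP19 rose by 2.69 ± 0.34 and TIMP3 by 3.94 ± 0.60. NRF2 targets (0.000219, 6 rising, 8 over the list alone), NF-kB regulators (0.000344, 6 rising, 9 over the list alone), MHC class I (0.000422, 6 rising, 7 over the list alone, with HLA-F 1.74 ± 0.23) and glycolysis (0.00152, 3 rising, 5 over the list alone) were also higher. Checkpoint ligands were higher (0.0247, 5 rising and 1 falling, 6 and 1 over the list alone), with the ectonucleotidase NT5E at 112 against 11.4 CPM (3.29 ± 0.39) and CD274, which encodes PD-L1, at 3.92 against 0.477 CPM (3.01 ± 0.56). Cholesterol biosynthesis was higher (0.0101, 4 rising, 5 over the list alone). Immature myeloid markers (0.000219, 3 falling with either adjustment) and cell cycle genes (0.00311, none falling, 12 falling with the block) were lower. The checkpoint call was lost without EV CM replicate 3 (0.0577), cell cycle without that library (0.066) or S14 CM replicate 1 (0.0686) or 2 (0.0861), and cholesterol without S14 CM replicate 1 (0.0961) or 2 (0.173). LXR targets were called only with the block (0.0482, against 0.114, and adjusted p = 0.193 with an estimated correlation), and MHC class II was not called (median -0.25, adjusted p = 0.393, 0 members).

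To set the activating receptor's line against the line named for the inhibitory one, S14 was compared with S5 in each medium. In mock cells IGFN1 (9.78 ± 0.66), the metalloproteinase inhibitor TIMP4 (chr3, 12153051 to 12159351; 7.91 ± 0.79), the metalloproteinase MMP7 (chr11, 102520508 to 102530753; 142 ± 100 against 0.777 CPM, 7.51 ± 1.43) and TFPI2 (chr7, 93885396 to 93890991; 7.43 ± 1.65) were higher in S14. F13A1 (-7.88 ± 0.59), C1QA (-5.59 ± 0.43), CCR2 (-5.56 ± 0.74), the granule protease CTSG (chr14, 24573522 to 24576260; -5.04 ± 0.98) and MPEG1 (-5.03 ± 0.46) were lower. In conditioned medium IGFN1 (10.36 ± 0.67), the somatostatin receptor SSTR2 (chr17, 73165012 to 73176633; 7.83 ± 0.70) and HES2 (7.63 ± 0.63) were higher, as was TFPI2 (19.7 ± 27.6 CPM against 3 counts in all S5 libraries together, a ratio of 419, exact Poisson 95% interval 143 to 2032) by edgeR (adjusted p = 0.00679) but not by limma-voom (0.103). F13A1 (-8.24 ± 0.63), SERPINB2, a plasminogen activator inhibitor (chr18, 63871692 to 63903890; -5.05 ± 1.03), MPEG1 (-4.32 ± 0.44), C1QA (-3.92 ± 0.40) and C1QC (-3.83 ± 0.39) were lower. ATP1B4 had no count in any S5 library, at least 115-fold below S14 in mock and 110-fold in conditioned medium by that floor.

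By edgeR, 3835 genes differed between S14 and S5 mock cells (2041 higher, 1794 lower) and 2460 in conditioned medium (1588 higher, 872 lower). With the block these counts were 6878 and 4744, in replicates 1 and 2 alone 9773 and 7573, and in fits of only the groups compared 1875 and 1194. The share of higher genes in conditioned medium was 64.6%, against 54.2% with the block and 76.3% in the fit of only these groups. In mock cells it was 53.2%, against 43.0% with upper-quartile scaling. Without S14 mock replicate 1 the mock count was 2514. Interferon-stimulated genes were higher in mock (median 0.64, adjusted p = 1.31e-06, and 0.12 with an estimated correlation, 19 rising, 20 adjusted over the list alone). They were higher in conditioned medium too (0.70, adjusted p = 1.18e-10, and 0.0429 with an estimated correlation, 21 rising, 25 over the list alone). The call at 0.0429 was lost in replicates 1 and 2. Inflammatory cytokines and chemokines were higher in both media (medians 2.74 and 2.35, adjusted p = 2.71e-06 and 1.24e-08, and adjusted p = 0.205 and 0.163 with an estimated correlation), 12 members rising in each, or 16 and 13 over the list alone with 1 falling in mock. Immature myeloid markers were lower in both (medians -2.60 and -2.11, adjusted p = 1.02e-06 and 4.71e-08, and adjusted p = 0.205 and 0.189 with an estimated correlation), 11 members falling in each, or 13 over the list alone.

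MHC class II genes were lower in S14 than in S5 mock cells (median -1.08, adjusted p = 0.000161, and adjusted p = 0.107 with an estimated correlation), 7 members falling, or 10 adjusted over the list alone. In conditioned medium the list gave a median of -0.63 (adjusted p = 0.0212, and adjusted p = 0.188 with an estimated correlation, 2 falling), a call lost without S14 CM replicate 3 (0.087) or S5 CM replicate 2 (0.0733). Integrated stress response genes were higher in S14 in conditioned medium (median 1.23, adjusted p = 1.24e-08, and adjusted p = 0.293 with an estimated correlation, 13 rising, 20 over the list alone). In mock cells this list was not called (adjusted p = 0.13), with a median of -0.05 and a mean of 0.28. Cholesterol biosynthesis was higher in conditioned medium (median 0.65, adjusted p = 2.23e-05, and adjusted p = 0.304 with an estimated correlation, 10 rising, 17 over the list alone). The other lists called with the preset correlation had adjusted p of 0.163 to 0.721 with an estimated one. They were matrix remodelling, NF-kB regulators, immediate early genes, NRF2 targets, hypoxia and glycolysis (higher in both media), cell cycle and ribosomal proteins (lower in both), histones (higher) and metallothioneins (lower) in mock, and MHC class I and checkpoint ligands (higher) in conditioned medium. With 1 library left out, calls were lost for metallothioneins (0.08 without S14 mock replicate 2, 0.0656 without S5 mock replicate 3, and 0.0791 in a fit of only these groups), histones (0.171 without S14 mock replicate 3, 0.0529 without S5 mock replicate 3, and 0.172 in replicates 1 and 2) and ribosomal proteins in mock (0.137 without S5 mock replicate 3). In conditioned medium they were lost for cell cycle (0.1 and 0.118 without S14 replicate 1 or 2, 0.248 without S5 replicate 3), checkpoint ligands (0.065 without S5 replicate 3) and ribosomal proteins (0.0912 without S14 replicate 1, 0.178 and 0.056 without S5 replicate 2 or 3). MHC class I in mock (0.0248, against 0.0976) and LXR targets in conditioned medium (0.021, against 0.0738) were called only with the block (adjusted p = 0.366 and 0.175 with an estimated correlation).

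To determine whether the line named for Siglec-5 differed from the empty-vector line, S5 and EV were compared in each medium. No gene was called by edgeR in mock cells (411 at an unadjusted p under 0.05) or in conditioned medium (543). By limma-voom 0 were called in both, and by DESeq2 4 and 6. With the replicate block 3 were called in mock cells and 0 in conditioned medium, and in replicates 1 and 2 alone 352 and 388. Besides SIGLEC14, the 3 were ANKH, a membrane transporter (4.25 ± 0.630 against 12.5 ± 2.87 CPM, adjusted p = 0.0893 without the block and 0.0246 with it), and CERCAM (23.5 ± 8.59 against 9.49 ± 4.34 CPM, adjusted p = 1 without the block and 0.0251 with it), both chosen after their values were seen. Without EV mock replicate 1, ANKH was called without the block (adjusted p = 0.041), as it was with no expression filter (0.045). The DESeq2 calls in mock cells included ANKH (-1.56), LBH (-1.71) and PDCD4 (0.64), also chosen after their values were seen.

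Gene lists differed between S5 and EV with the preset correlation, and none did with an estimated one (lowest adjusted p = 0.232 in mock and 0.184 in conditioned medium). Immature myeloid markers were higher in S5 in both media (medians 0.75 and 0.98, adjusted p = 1.27e-06 and 3.97e-07, and adjusted p = 0.508 and 0.328 with an estimated correlation). Their medians were 0.31, 0.27 and 1.41 in replicates 1, 2 and 3 in mock, and 0.25, 0.37 and 1.88 in conditioned medium. Without S5 replicate 3 the call was lost in each (adjusted p = 0.288 and 0.208). Inflammatory cytokines and chemokines were lower in both (medians -0.89 and -0.95, adjusted p = 0.00191 and 5.37e-07, and adjusted p = 0.515 and 0.328 with an estimated correlation), with replicate medians of 0.11, -0.44 and -1.44 in mock. This was lost without EV replicate 3 (0.491 and 0.0624) and in replicates 1 and 2 (0.588 and 0.316). Interferon-stimulated genes were higher in both (medians 0.26 and 0.15, adjusted p = 1.27e-06 and 0.0062, and adjusted p = 0.232 and 0.368 with an estimated correlation). In conditioned medium this was lost without EV replicate 2 (0.0724) or S5 replicate 1 (0.0538). No member of these lists was called over all genes, and over the list alone 1 inflammatory member fell in conditioned medium.

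MHC class II genes were higher in S5 cells (medians 0.21 and 0.30, adjusted p = 0.0291 and 0.000941, and adjusted p = 0.508 and 0.184 with an estimated correlation). NF-kB regulators were lower (0.00313 in mock, 6.63e-05 in conditioned medium), as were matrix remodelling (0.00313 and 0.000325), cholesterol biosynthesis (0.0448 and 6.21e-05) and alternative activation markers (0.0469 and 0.00407). Metallothioneins were higher in both (0.00489 and 0.0457). In mock cells glycolysis (0.00313), hypoxia (0.00389), oxidative phosphorylation (0.0321) and ribosomal proteins (0.0469) were higher. These lists gave adjusted p = 0.328 to 0.749 with an estimated correlation. CD163, the haemoglobin scavenger receptor, was the 1 alternative activation member lower over the list alone in conditioned medium (56.4 against 177 CPM, -1.65 ± 0.36, adjusted p = 0.81 over all genes). With the block, cholesterol and alternative activation were not called in mock (0.0551 each), while MHC class I was (0.0271, against 0.0512), and ribosomal proteins were called in conditioned medium (0.0278, against 0.0513), with adjusted p = 0.512 and 0.869 with an estimated correlation.

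In S5 against EV mock cells, calls were lost without S5 mock replicate 3 for MHC class II (0.136), NF-kB regulators (0.186), matrix remodelling (0.904), cholesterol (0.136), metallothioneins (0.492), alternative activation (0.994), oxidative phosphorylation (0.288) and ribosomal proteins (0.134), the last 3 with their direction turned. Without EV mock replicate 3 they were lost for NF-kB regulators (0.468), matrix remodelling (0.07), glycolysis (0.149), hypoxia (0.263), cholesterol (0.0639) and alternative activation (0.07). Without EV mock replicate 1 or 2 they were lost for MHC class II (0.136 and 0.141), cholesterol (0.234 and 0.0675), alternative activation (0.123 and 0.2), metallothioneins (0.0893 and 0.0813), oxidative phosphorylation (0.398 and 0.63) and ribosomal proteins (0.728 and 0.948). Without S5 mock replicate 1, MHC class II (0.0592), glycolysis (0.0935) and hypoxia (0.224) were lost, and without S5 mock replicate 2, cholesterol (0.23) and hypoxia (0.124). In conditioned medium, NF-kB regulators and matrix remodelling were lost without EV replicate 3 (0.172 and 0.0759) or S5 replicate 3 (0.0978 and 0.0681). Alternative activation was lost without S5 replicate 3 (0.622), and metallothioneins without that library (0.616) or EV replicate 1 (0.108) or 2 (0.322). In replicates 1 and 2 alone, alternative activation (0.728 in mock, 0.316 in conditioned medium), matrix remodelling (0.584 and 0.316), NF-kB regulators (0.894 and 0.996), oxidative phosphorylation in mock (0.244) and ribosomal proteins in mock (0.337) were not called, and matrix remodelling and NF-kB regulators turned direction in mock. Relative log expression ended the mock calls of alternative activation and ribosomal proteins (0.0504 each), upper-quartile scaling that of alternative activation (0.055) and a fit of only these groups that of ribosomal proteins (0.0888). The cell cycle list in mock cells had a median of 0.22 and a test pointing down (adjusted p = 0.56), and in replicates 1 and 2 it was lower (adjusted p = 3.46e-21, and adjusted p = 0.247 with an estimated correlation, 16 members falling).

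To determine how empty-vector macrophages responded to tumour medium, conditioned and mock medium were compared in EV cells. C3, the central complement component (chr19, 6677704 to 6730562), rose from 214 ± 31.1 to 564 ± 59.1 CPM (1.40 ± 0.17, adjusted p = 0.00697), by 1.46, 1.40 and 1.34 in replicates 1, 2 and 3. It was the only gene called by edgeR (267 at an unadjusted p under 0.05), and by DESeq2 and limma-voom. The call was lost without EV CM replicate 3 (0.0836), without EV mock replicate 1 (0.174) or 2 (0.171), and in a fit of only these groups (0.329). With the replicate block CAPG, an actin-capping protein chosen after its values were seen, was called too (109 ± 26.4 to 274 ± 47.9 CPM, adjusted p = 0.00571, against 1 without the block). With replicates 1 and 2 alone 566 genes were called (221 higher, 345 lower).

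The integrated stress response list was higher in EV cells in conditioned medium (median 0.30, 24 of 29 above 0, adjusted p = 0.000686, and 0.855 with an estimated correlation). Its members CHAC1 (1.28 ± 0.77) and PSPH (0.63 ± 0.36) were not called. The list's medians were 0.33, 0.58 and -0.01 in replicates 1, 2 and 3. In replicates 1 and 2 alone 16 members rose and 2 fell. Alternative activation markers were lower (median -0.13, adjusted p = 0.00125, and 0.737 with an estimated correlation), with 1 member falling over the list alone. FOLR2 (-1.05 ± 0.27), LYVE1 (-1.87 ± 0.55) and the scavenger receptor STAB1 (81.3 to 41.5 CPM, -0.97 ± 0.40) had adjusted p = 1. Ribosomal proteins were higher (0.0158), and immediate early genes (0.0158) and ER chaperones (0.0439) were lower, with adjusted p = 0.855 to 0.995 with an estimated correlation. The ribosomal call was lost without EV CM replicate 3 (0.472) or EV mock replicate 1 (0.485) or 2 (0.744). Immediate early genes lost theirs without EV CM replicate 2 (0.0662) or 3 (0.0729) or EV mock replicate 2 (0.178), and ER chaperones without EV CM replicate 1 (0.151) or 2 (0.307) or EV mock replicate 3 (0.294). Only with the block were mitochondrially encoded genes (0.00595, against 0.0741) and cell cycle genes (0.00351, against 0.116) called as higher (adjusted p = 0.97 with an estimated correlation). No list member was called over all genes in EV cells, nor any of these 3 lists' members over the list alone.

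In S5 cells C3 also rose in conditioned medium, from 185 ± 15.2 to 447 ± 37.6 CPM (1.27 ± 0.17, adjusted p = 0.0221), by 1.25, 1.25 and 1.31 in replicates 1, 2 and 3. It was the 1 gene called by edgeR (347 at an unadjusted p under 0.05). Its call was lost without any 1 of the 6 libraries, namely S5 CM replicate 1 (0.214), 2 (0.0591) or 3 (0.149) or S5 mock replicate 1 (0.153), 2 (0.4) or 3 (0.114), and in a fit of only these groups (0.763). THBS1, thrombospondin-1, chosen after its values were seen, went from 8.99 ± 6.35 to 0.439 ± 0.378 CPM (-4.28 ± 0.72, adjusted p = 0.198). It was called by DESeq2 (1.12e-06) and without S5 mock replicate 3 (0.00542). With replicates 1 and 2 alone 1259 genes were called (512 higher, 747 lower). Alternative activation markers were lower (median -0.24, adjusted p = 6.77e-05, and 0.283 with an estimated correlation), with 4 members falling over the list alone and 0 over all genes. STAB1 (-1.29 ± 0.40), CD163 (-0.80 ± 0.36), the lipid chaperone FABP4 (237 to 68.9 CPM, -1.78 ± 0.61) and C1QC (-0.94 ± 0.34) had adjusted p = 1. Without S5 CM replicate 3 the list was not called (0.252).

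Integrated stress response genes were higher in S5 cells in conditioned medium (median 0.26, adjusted p = 0.000282, and 0.707 with an estimated correlation), and in replicates 1 and 2 alone 16 members rose and 3 fell. Without S5 mock replicate 1 or 2 this was lost (0.075 and 0.0863). Interferon-stimulated genes (median -0.10) and ER chaperones (median -0.18) were lower (adjusted p = 0.000282 each, and 0.353 with an estimated correlation). The remaining called lists were mitochondrially encoded genes (0.00542), ribosomal proteins (0.00864) and cell cycle genes (0.0484), higher, and immediate early genes (0.00617), glycolysis, hypoxia and macrophage identity (0.0484 each), lower. They had adjusted p = 0.707 to 0.748 with an estimated correlation. Mitochondrially encoded genes, ribosomal proteins and cell cycle genes lost their calls without S5 CM replicate 3 (0.441, 0.298 and 0.314), S5 mock replicate 1 (0.304, 0.304 and 0.944) or S5 mock replicate 2 (0.273, 0.976 and 0.955), with the direction of cell cycle turned in each and that of ribosomal proteins in the last. Ribosomal proteins were also lost without S5 CM replicate 2 (0.607). Immediate early genes, glycolysis, hypoxia and macrophage identity lost theirs without S5 CM replicate 3 (0.998, 0.231, 0.998 and 0.713, hypoxia turning direction), S5 mock replicate 1 (0.304, 0.507, 0.763 and 0.551) or S5 mock replicate 2 (0.178, 0.0501, 0.395 and 0.357), and glycolysis also without S5 CM replicate 1 (0.102) or 2 (0.063). Macrophage identity was not called with the block (0.0888, and 0.261 in each line), and cell cycle not with upper-quartile scaling (0.0786). Relative log expression ended the calls of glycolysis (0.0526), hypoxia and macrophage identity (0.0563 each).

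To ask how S14 cells responded to tumour medium, conditioned and mock medium were compared in that line. ALDH2, mitochondrial aldehyde dehydrogenase (chr12, 111766887 to 111817529), rose from 9.61 ± 3.07 to 36.9 ± 12.1 CPM (1.94 ± 0.29, adjusted p = 0.0381), by 2.54, 2.39 and 0.82 in replicates 1, 2 and 3. HSD11B1, which regenerates active glucocorticoid (chr1, 209686178 to 209734950), rose from 5.77 ± 0.537 to 18.9 ± 6.59 CPM (1.71 ± 0.26, adjusted p = 0.0381). MCEMP1 (chr19, 7676628 to 7679826; 4.87 ± 1.69 to 14.8 ± 3.35 CPM), SNN (chr16, 11668414 to 11679159; 17.3 ± 0.519 to 34.9 ± 3.98) and the zinc transporter SLC39A11 (chr17, 72645949 to 73092712; 62.5 ± 12.1 to 108 ± 9.84) also rose. Of the other called genes, chosen after their values were seen, ATP8B1 (1.44 ± 0.23), LINC01305 (0.86 ± 0.14) and ENSG00000253141 (3.07 ± 0.50) rose and RGS4, a brake on G protein signalling, fell from 6.12 to 0.984 CPM (-2.62 ± 0.43). C3 stood at 510 ± 29.5 and 894 ± 206 CPM (0.81 ± 0.17, adjusted p = 0.0605).

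These 9 genes (8 higher, 1 lower) were all that edgeR called in S14 cells, with 2982 at an unadjusted p under 0.05. Limma-voom called 0 and DESeq2 874, the replicate block 1956 (982 higher, 974 lower), and replicates 1 and 2 alone 8066 (3867 higher, 4199 lower). None was called without S14 CM replicate 1 or 2 or S14 mock replicate 1 or 2, or in a fit of only these groups, where the 5 genes named by rule had adjusted p = 0.46. By limma-voom these 5 had 0.082, and ALDH2 had 0.199 and 0.239 without S14 CM replicate 1 and 2, and 0.319 and 0.293 without S14 mock replicate 1 and 2. Without S14 CM replicate 3 the count was 1408, and without S14 mock replicate 3 it was 2043.

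Integrated stress response and amino acid supply genes were higher in S14 cells in conditioned medium (median 1.09, 25 of 29 above 0, adjusted p = 4.52e-11, and 0.535 with an estimated correlation). None was called over all genes, 23 rose and 1 fell over the list alone, and 19 rose and 1 fell with the block. The serine synthesis enzyme PHGDH went from 26.1 to 225 CPM (3.11 ± 0.64), SLC7A5 from 95.0 to 374 (1.98 ± 0.41) and TRIB3 from 32.2 to 175 (2.44 ± 0.51). Each had adjusted p = 0.061, and PHGDH 0.017 with the block. The list's medians were 1.44, 1.61 and 0.13 in replicates 1, 2 and 3. MALAT1's share of counts went from 0.082 to 1.16%, 0.086 to 0.375% and 0.054 to 0.046%. A link was not tested. All 11 MHC class II genes had higher estimates (median 0.78, adjusted p = 0.00102, and 0.144 with an estimated correlation), the only list called by fry (0.00325). Of these 0 rose over all genes and 4 over the list alone, and 4 with the block, and HLA-DRB1 went from 43.7 to 70.3 CPM (0.69 ± 0.19, adjusted p = 0.091, and 0.018 with the block).

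All 40 cell cycle genes had higher estimates in S14 cells in conditioned medium (median 0.61, adjusted p = 0.000742, and 0.703 with an estimated correlation), 0 rising with either adjustment, 11 with the block and 35 in replicates 1 and 2. Their medians were 1.44, 1.66 and 0.32 in replicates 1, 2 and 3. Mitochondrially encoded genes were higher (median 0.45, adjusted p = 0.00296), with replicate medians of 1.04, 1.01 and -0.08, as were ribosomal proteins (median 0.23, 0.00716) and cholesterol biosynthesis (median 0.32, 0.0391). Histones (median -0.48, 0.00887), glycolysis (median -0.16, 0.0165) and ER chaperones (median -0.16, 0.0445) were lower. These 6 lists had adjusted p = 0.535 to 0.703 with an estimated correlation and no member called over all genes. Over the list alone 1 cholesterol member rose, and 4 glycolysis and 3 ER chaperone members fell. Without S14 CM replicate 3, S14 mock replicate 1 or S14 mock replicate 2 the calls were lost for cell cycle (0.603, 0.0855 and 0.137), mitochondrial genes (0.176, 0.084 and 0.133) and ribosomal proteins (0.24, 0.166 and 0.117). Histones were lost without S14 CM replicate 2 (0.0706) or S14 mock replicate 3 (0.262), and glycolysis without S14 mock replicate 2 (0.133). Cholesterol and ER chaperones were lost without S14 CM replicate 1 (0.278 and 0.173) or 2 (0.534 and 0.152) or S14 mock replicate 3 (0.712 and 0.504), and in a fit of only these groups (0.0774 and 0.0912), as was glycolysis (0.052, and 0.0618 with a block in each line). In replicates 1 and 2 alone ER chaperones (0.0511) and histones (0.0513) were not called. The hypoxia list was called as lower only with the block (0.0154, against 0.0956, and adjusted p = 0.698 with an estimated correlation).

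**Figure D3:**
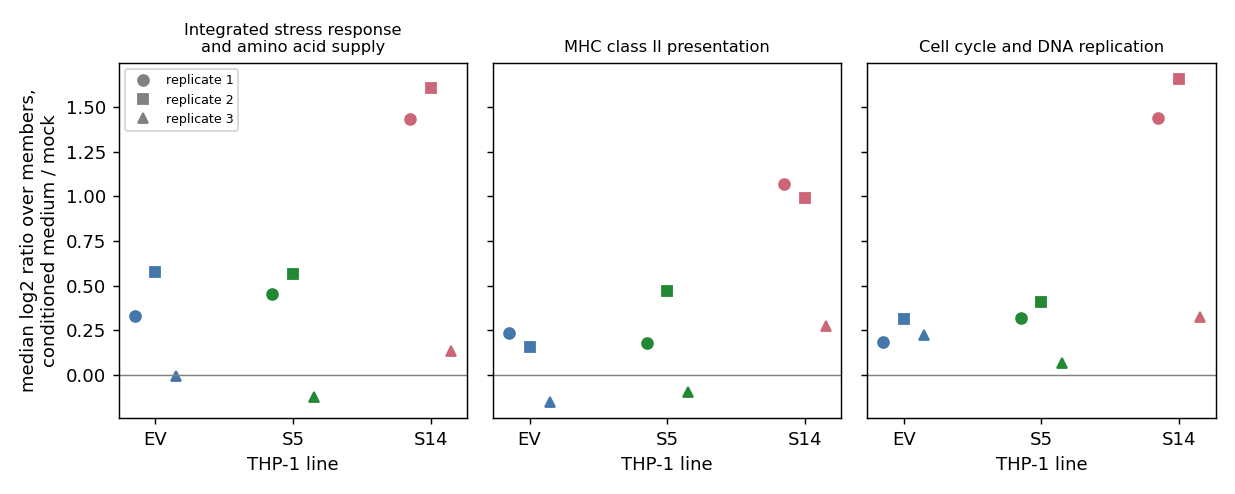
Median log2 ratio of conditioned to mock medium over the members of 3 gene lists (integrated stress response, MHC class II, cell cycle), for each line, with 1 point per replicate number. In S14 cells replicate 3 lies lowest in each list.

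To ask whether Siglec-14 or Siglec-5 cells responded to tumour medium differently from the other lines, the differences in response were tested. No gene was called by edgeR for S14 minus EV (812 at an unadjusted p under 0.05), S14 minus S5 (628) or S5 minus EV (48), nor by limma-voom or with the replicate block. DESeq2 called 3, 2 and 0, chosen after their values were seen: RGS4 (-3.25 for S14 minus EV, -3.31 for S14 minus S5) and ENSG00000253141 (3.07 and 3.24) in both, and GAL3ST4 (-2.59) for S14 minus EV. In replicates 1 and 2 alone 4328, 3898 and 0 genes were called. Without S14 CM replicate 3 the count was 41 for S14 minus EV and 26 for S14 minus S5, and without S14 mock replicate 3 it was 107 and 45. For C3 the difference between S14 and EV was -0.59 ± 0.23 and between S5 and EV -0.13 ± 0.23 (adjusted p = 1 each).

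The integrated stress response list rose more in S14 than in EV (median difference 0.81, adjusted p = 1.43e-07, and 0.605 with an estimated correlation) and than in S5 cells (0.86, adjusted p = 3.09e-08, and 0.487 with an estimated correlation). No member was called, over all genes or over the list alone, and TRIB3 (2.36 ± 0.69), ASNS (3.16 ± 0.99) and PHGDH (2.22 ± 0.85) had adjusted p = 1 for S14 minus EV. MHC class II likewise had a more positive response in S14 (0.73 against EV, adjusted p = 0.000484, and 0.0922 with an estimated correlation, and 0.54 against S5, adjusted p = 0.00213, and 0.192 with an estimated correlation). Both lists kept their calls without any 1 library, but the difference was small in replicate 3. Against EV the stress response medians were 1.19, 0.94 and 0.24 in replicates 1, 2 and 3 and those of MHC class II 0.89, 0.66 and 0.27, alongside 0.59, 0.76 and -0.07 for mitochondrially encoded genes. Against S5 the stress response gave 1.01, 0.95 and 0.26.

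Other differences in response were less stable. Histones responded more negatively in S14 than in EV (-0.49, adjusted p = 0.00444, and 0.494 with an estimated correlation) and than in S5 cells (-0.50, adjusted p = 0.000301, and 0.192 with an estimated correlation), both lost without S14 mock replicate 3 (0.182 and 0.0622). Cell cycle genes responded more positively in S14 than in EV (0.37, adjusted p = 0.0129, and 0.784 with an estimated correlation) and than in S5 (0.43, adjusted p = 0.0126, and 0.875 with an estimated correlation). Both were lost without S14 CM replicate 3 (0.954 and 0.824, direction turned) or S14 mock replicate 1 (0.393 and 0.509) or 2 (0.596 and 0.736). The first was also lost without EV CM replicate 1 (0.0669) or 2 (0.14) or EV mock replicate 3 (0.198), and the second without S5 CM replicate 1 (0.171) or 2 (0.24) or S5 mock replicate 3 (0.866). Glycolysis responded more negatively in S14 than in EV (-0.26, adjusted p = 0.0129, and 0.605 with an estimated correlation), lost without EV CM replicate 1 (0.0648), EV mock replicate 3 (0.137) or S14 mock replicate 2 (0.159).

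Against S5, cholesterol biosynthesis responded more positively in S14 (0.39, adjusted p = 0.0016, and adjusted p = 0.662 with an estimated correlation), lost without S14 CM replicate 2 (0.151) or S14 mock replicate 3 (0.326). Metallothioneins did too (1.22, adjusted p = 0.0344, and adjusted p = 0.662 with an estimated correlation), lost without S14 CM replicate 3 (0.283), S14 mock replicate 1 (0.0766) or 2 (0.236), S5 CM replicate 1 (0.144) or 2 (0.113) or S5 mock replicate 3 (0.383). Alternative activation markers responded more positively in S14 than in S5 (0.24, adjusted p = 0.0299, and adjusted p = 0.487 with an estimated correlation), with FOLR2 passing over the list alone (2.15 ± 0.46, adjusted p = 0.98 over all genes). This call was lost without S14 CM replicate 3 (0.283), S14 mock replicate 2 (0.0529) or 3 (0.0631), S5 CM replicate 3 (0.256) or S5 mock replicate 1 (0.115) or 2 (0.0815), in replicates 1 and 2 (0.255) and with a block in each line (0.0623). For S5 minus EV no list was called by camera (lowest adjusted p = 0.0687) or fry, against 8 in replicates 1 and 2 alone, 11 without S5 mock replicate 3 and 1 to 6 without any of 9 other libraries. With the block hypoxia (0.000481) and glycolysis (0.0428) were called for S5 minus EV, mitochondrial genes (0.00945), hypoxia (0.0098) and metallothioneins (0.0199) for S14 minus EV, and mitochondrial genes for S14 minus S5 (0.0417) (adjusted p = 0.711 to 0.962 with an estimated correlation).

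As a check on RNA carried over with the tumour medium, colorectal epithelial markers were examined. EPCAM and KRT19 had 0 counts in all 18 libraries. The summed markers stood at 17.9 ± 4.85 CPM in EV mock, 19.8 ± 6.39 in S5 mock, 10.7 ± 2.06 in S14 mock, 19.2 ± 4.46 in EV conditioned medium, 22.8 ± 8.30 in S5 conditioned medium and 23.4 ± 9.84 in S14 conditioned medium. Only 4 markers were expressed enough to be tested, too few for a list test. S100P was higher in S14 than in EV cells in conditioned medium (4.39 ± 1.06, adjusted p = 0.0125) and than in S5 cells (3.72 ± 1.01, adjusted p = 0.0212), and was not called for conditioned medium in S14 (4.01 ± 1.03, adjusted p = 0.0781).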

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

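The tests of a replicate batch, of both explanations for SIGLEC5, and of normalization and replicate batch for the S14 against EV difference, and the splits balanced by replicate number for differences in response, were chosen only after the result was seen; the depth tests and the other counts over splits of the samples were set down before.

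The response to conditioned medium differed between lines for 12 list results, each picked out because the test of the difference itself was passed with the preset correlation. For S14 minus EV these were the integrated stress response (adjusted p = 1.43e-07), MHC class II (0.000484), histones (0.00444), cell cycle (0.0129) and glycolysis (0.0129). For S14 minus S5 they were the integrated stress response (3.09e-08), histones (0.000301), cholesterol biosynthesis (0.0016), MHC class II (0.00213), cell cycle (0.0126), alternative activation (0.0299) and metallothioneins (0.0344). With an estimated correlation none passed (adjusted p = 0.0922 to 0.875). Of 33 splits of the 12 libraries, 25 called at least as many lists as the real 5 for S14 minus EV (highest other 13) and 25 at least as many as the real 7 for S14 minus S5 (highest other 14), so chance is not excluded by them. For S5 minus EV the real count was 0 lists, which every split reaches by definition (highest other 13). Counts of called genes were 0 in all 3 differences, which 33 of 33 splits reached, and the highest other counts were 1, 1 and, for S14 minus S5, 2137. A split that calls 2137 genes points to a structure of the samples. Most of these splits mix replicate numbers. Of all 32 that keep a library of each number on each side, 16 called at least 5 lists for S14 minus EV and 9 at least 7 for S14 minus S5 (highest other 10 each), and all 32 at least 0 for S5 minus EV (highest other 10). All others that reach 7 for S14 minus S5 keep or reverse a line whole and so carry its response. Of the 18 that mix both lines, 6 reached the real 5 for S14 minus EV (highest 7) and 0 the real 7 for S14 minus S5 (highest 6), too few for a share under 0.05, and with the block 2 of 18 reached the real 8 in each.

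Replicate 3 stood apart from replicates 1 and 2 in all 6 groups. A batch shared by the replicate 3 libraries predicts that they deviate together across groups, and the lowest correlation of deviations among them was 0.384. Sequencing depth as the whole cause is argued against, since that correlation was 0.393 after every library was thinned to the smallest total. The pattern is consistent with a shared day of culture, RNA preparation or sequencing, which may hold technical and biological differences that the labels do not record. No biological explanation was tested.

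SIGLEC5 counts stayed low in the line named for Siglec-5 (10 to 20 per library). That the S5 libraries were empty-vector cells is argued against, since the lowest S5 library held 1.30 times the SIGLEC14 CPM of the highest EV library. A loss of reads to overlapping models and to SIGLEC14 predicts few bases that count for SIGLEC5 alone, and 0% of its 100-base coding windows did so in GENCODE 29. This may account for the low SIGLEC5 counts, and the raised SIGLEC14 counts in S5 cells could be reads of the introduced SIGLEC5. Neither was tested on reads, and the annotation used for counting is not given in the sources used here.

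The S14 line differed from the EV line in 3575 genes in mock cells. Normalization as the whole cause is argued against by 3589 calls, the fewer of 2 other scalings, and sequencing depth by 3394 calls after thinning all libraries to the smallest total. The 6672 calls with the replicate block are no test of a batch, since each replicate number occurs once in each group. Siglec-14 and any other difference between the lines cannot be told apart, because only 1 line carried Siglec-14.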

How the results depend on the processing

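Replicates 1 and 2 alone, the block within each line and the block with an estimated correlation were chosen only after seeing the data; the other settings were fixed with the design. With 3 libraries a group, a shared structure of replicate 3, counts of called genes depended on the spread a fit assumes, and list calls on the correlation assumed between genes; the cause of the other shifts was not tested. The settings listed for normalized values (among them a pseudocount) were not run, because the deposited values are counts. Of results for named genes, 0 were lost with relative log expression, 14 without a filter, 11 with limma-voom, 5 with upper-quartile scaling and 40 in fits of only the groups compared. With the replicate block 43 named-gene results newly passed and 0 were lost, 4 list calls were lost, and it changed no other call beyond those in the report. Of list calls, 112 of 117 held with relative log expression, 114 with upper-quartile scaling, 3 with an estimated correlation and 51 with fry.

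Counts of called genes with the replicate block were 2 for conditioned medium in EV (1 without) and 1956 in S14 cells (9), 3 for S5 against EV in mock (0), 6672 for S14 against EV in mock (3575) and 4207 in conditioned medium (1990), and 6878 (3835) and 4744 (2460) for S14 against S5; lists numbered 8 for S14 minus EV (5) and 2 for S5 minus EV (0). With a block in each line, 24, 14 and 3730 genes were called for conditioned medium in EV, S5 and S14, 46 for S14 minus EV and 16 for S14 minus S5, and 10, 10 and 4 lists for EV, S14 minus EV and S5 minus EV. In replicates 1 and 2 alone, counts were 566, 1259 and 8066 for conditioned medium in EV, S5 and S14, 352 and 388 for S5 against EV in mock and conditioned medium, 9921 and 7825 for S14 against EV, 9773 and 7573 for S14 against S5, 4328 for S14 minus EV and 3898 for S14 minus S5, with 9 lists for S14 minus EV and 8 for S5 minus EV. Fits of only the groups compared called 0 genes for conditioned medium in each line (unadjusted p under 0.05 for 550, 296 and 1737), 1875 and 1194 for S14 against S5, and 8 lists for EV and 3 for S5 minus EV. DESeq2 called 2 genes for conditioned medium in S5 and 874 in S14, 4 and 6 for S5 against EV, 3 for S14 minus EV and 2 for S14 minus S5. For conditioned medium in S14, limma-voom called 0, a mean of at least 1 CPM 75 and no filter 38; no filter called 1 for S5 against EV in mock.

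With an estimated correlation camera called 1 list each for S14 against EV in both media and S14 against S5 in conditioned medium, and 0 elsewhere. With the block and an estimated correlation it called 1 for S14 against EV in conditioned medium and 0 elsewhere. Fry called 1 list for conditioned medium in S14, 0 in EV and S5, and 0 for S5 against EV and differences in response. It called more than camera's preset did for S14 against EV (19 in mock and 18 in conditioned medium, against 14 and 14) and for S14 against S5 (19 and 19, against 14 and 16).

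Direction turned for 10 list results with 1 library left out and 2 in replicates 1 and 2. Without S5 mock replicate 3, S5 against EV in mock gave adjusted p of 0.994 for alternative activation, 0.288 for oxidative phosphorylation and 0.134 for ribosomal proteins; in replicates 1 and 2 it gave 0.584 for matrix remodelling and 0.894 for NF-kB regulators. Cell cycle gave 0.954 for S14 minus EV and 0.824 for S14 minus S5 without S14 conditioned medium replicate 3. For conditioned medium in S5, cell cycle gave 0.314 without conditioned medium replicate 3 and 0.944 and 0.955 without mock replicates 1 and 2, hypoxia 0.998 without conditioned medium replicate 3, and ribosomal proteins 0.976 without mock replicate 2. Over all single omissions these results lay between 0.00913 and 0.994 for alternative activation, 1.16e-05 and 0.63 for oxidative phosphorylation and 7.9e-07 and 0.948 for ribosomal proteins (S5 against EV in mock). Cell cycle lay between 1.64e-09 and 0.954 (S14 minus EV), 5.5e-10 and 0.866 (S14 minus S5) and 3.35e-07 and 0.955 (conditioned medium in S5), where hypoxia lay between 0.000119 and 0.998 and ribosomal proteins between 3.03e-08 and 0.976.

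Leaving out 1 library at a time gave 0 to 1 genes for conditioned medium in EV and in S5, 0 to 2043 in S14 and 0 to 1 for S5 against EV in mock (0 in conditioned medium). It gave 2264 to 4939 and 1164 to 2114 for S14 against EV in mock and conditioned medium, 2514 to 5242 and 1690 to 2540 for S14 against S5, 0 for S5 minus EV, 0 to 107 for S14 minus EV and 0 to 45 for S14 minus S5. Lists ranged from 4 to 10 for conditioned medium in EV, 3 to 15 in S5, 5 to 9 in S14, 6 to 13 and 5 to 12 for S5 against EV, 13 to 17 and 12 to 17 for S14 against EV, 14 to 15 and 14 to 16 for S14 against S5, and 0 to 11, 3 to 10 and 4 to 10 for S5 minus EV, S14 minus EV and S14 minus S5.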

Other observations

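The comparison of replicate 3 with replicates 1 and 2 was chosen only after the result was seen; both hypotheses below and the counts over other splits were set down before.

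Replicate 3 cells differed from the others in many gene groups, over all lines and media. With line and medium in the edgeR model, 4653 genes were higher and 4674 lower in replicate 3 (9327 of 17851). Cell cycle genes were higher in 38 of 40 cases (median 1.95 on the log2 scale), oxidative phosphorylation genes in 30 of 35 (0.44), all 13 mitochondrially encoded genes (0.78), 24 of 30 ribosomal protein genes (0.27) and all 6 metallothioneins (1.07). Hypoxia response genes were lower in 17 of 23 cases (-0.85). Inflammatory cytokines (13 higher and 3 lower, adjusted p = 0.0225), MHC class I (10 and 1, 0.0225) and ER chaperones (13 and 3, 0.0249) were higher. These lists were called by camera with the preset correlation and not with an estimated one (adjusted p = 0.567 for ribosomal proteins and inflammatory cytokines and 0.507 for the others).

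A first hypothesis was that conditioned medium partly undoes the S14 against EV difference. It predicts a negative correlation across genes between that difference in mock cells and the S14 response, with no library shared. The 6 such correlations lay between -0.412 and -0.0259, all negative. The 4 with the response of replicates 1 or 2 were below the bound of -0.1 set for all 6. Both with that of replicate 3 were not, so the prediction was not met in full and the hypothesis stays open. In S5 cells the measure lay between -0.0345 and 0.102.

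A further hypothesis was a response to conditioned medium shared by EV and S14 cells. The correlations across genes between both responses, with no library shared, lay between -0.0649 and 0.378. The 2 below 0 were those with EV replicate 3, so a response shared in every pairing was not seen and the hypothesis stays open.

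For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Called genes numbered 1 in the real split and 0 in the highest other for conditioned medium in EV and in S5 cells. For S14 against EV they were 3575 and 0 in mock and 1990 and 0 in conditioned medium, and for S14 against S5 3835 and 0, and 2460 and 0. For S5 against EV the real split called 0 genes in either medium, as did all 10 splits. For conditioned medium in S14 cells 2 of 10 splits gave at least the real 9, the other calling 234 with S14 mock replicates 1 and 2 and conditioned medium replicate 2 on a side. That split points to a structure of the samples. It holds both replicate 3 libraries on 1 side, but 3 other splits that do so called 0, and the cause was not tested. Among the 3 other splits that part as many replicate pairs as the real one, the highest count with the block was 3, against 1956 in the real split.

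Called lists, with the preset correlation, were as numerous in at least 1 other split of the 10 as in the real one for 6 of 9 comparisons. Real and highest other were 5 and 9 for conditioned medium in EV (5 of 10 splits as large), 11 and 14 in S5 (3 of 10) and 9 and 10 in S14 cells (4 of 10). For S5 against EV they were 13 and 12 in mock (1 of 10) and 9 and 11 in conditioned medium (5 of 10). For S14 against EV they were 14 and 14 (2 of 10) and 14 and 10 (1 of 10), and for S14 against S5 14 and 14 (2 of 10) and 16 and 11 (1 of 10). Among the 3 other splits with a library of each number on each side, the highest counts in the same order were 3, 6, 7, 11, 11, 12, 10, 11 and 11, below the real one except for S5 against EV in conditioned medium. With the replicate block the real count exceeded them in 5 of 9. All these splits are too few for a share under 0.05.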
